A study of Escherichia coli with 12 samples.

How the data were processed

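Total RNA of 12 E. coli samples was hybridised as labelled cDNA to E. coli antisense GeneChips (Affymetrix), 1 array per sample, per the labels. Per the labels, the authors computed signals with Microarray Suite 5.0 and scaled each array to a target intensity of 500, so the deposited values are intensity on a linear scale, already normalized. The mean between the 2nd and 98th percentile lay near 507 on all arrays. Groups, FeSO4 (50 uM) and arabinose (0.1%) were taken from the labels. The time between arabinose and sampling is not given in the sources used here. Detection calls were not used here. Scaling each array to 1 target assumes similar total signal, so a shift of abundant RNAs in 1 background moves all other values there.

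The table holds 7231 probe sets, 2886 of them intergenic. Of 4345 with a locus tag in their ID, 4183 matched a gene of the RefSeq table of assembly ASM584v2 and took its symbol, and 162 kept the name in the file. The platform annotation lists 4398 probe sets, 3804 with 1 distinct symbol and 594 with several, which come from several strains. Names were therefore taken from the locus tag, whose RefSeq gene ID was in the annotation for 4142 of 4151 tags. Probe sets shared between sequences number 371, and 0 carry the ryhB tag. The genome build behind the intergenic IDs is not given in the sources used here, so no coordinates are printed. No 2 of the 66 pairs of arrays were identical.

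Values were log2(signal + 50). Probe sets with a signal of at least 200 on at least 2 arrays were tested, which left 3707 (2842 genes, 865 intergenic) and removed 3524. One mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), so the 6 groups share 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg, called under 0.05. The 8 comparisons were RyhB against vector averaged over backgrounds and within each, the fur mutation and FeSO4 within vector strains, and 2 differences of the RyhB effect. Of 25 gene lists written beforehand, 24 had at least 4 tested genes and entered limma's camera (preset correlation 0.01, 1 probe set per gene) with Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry, which does not compare a list with other genes, stood beside it. All of this, with the alternatives in the closing section unless said otherwise, was fixed before the data were examined.

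Named genes are, per comparison, the 10 largest falls and 10 largest rises past the threshold among probe sets with 1 symbol whose groups do not overlap (same direction in all 3 backgrounds for the average), 5 each way for the differences, or the 3 smallest p-values if none pass. Members of the RyhB target lists, the 2 to 4 list members that moved furthest, fur and the arabinose genes were added. Some of the genes lower in all 3 backgrounds (such as pepB, pflA and trxA) and iscR fall outside this rule and were singled out after their values were seen.

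The scripts were tested on simulated data, with 200 of 3707 probe sets changed by known amounts around the real means and spreads. In the average RyhB effect, 98% of log2 changes of 1 and 100% of log2 changes of 2 were recovered, with 5 false calls among 203. In wild type the shares were 81% and 98% (7 false among 186), in the fur mutant 78% and 99% (12 among 189) and with FeSO4 82% and 100% (8 among 190). For the difference between fur mutant and wild type they were 53% and 97% (5 false among 155). A list of 14 genes shifted by -0.5 was called in 20 of 20 simulations, and 1 of 460 tests of other lists was called. These simulated genes vary independently, unlike real ones.

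Alternatives were pseudocounts of 10 and 1, quantile normalization, median centring, no filter, a mean signal of at least 400, no intensity trend, a replicate block, the compared groups fitted alone, the submitters' ratio rule (group means over 2-fold apart, the higher at least 200), and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.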

Results

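RNA of 12 Escherichia coli samples was measured on 1-colour oligonucleotide arrays, 1 array per sample. All strains derive from MG1655, a K-12 laboratory strain, lack the chromosomal ryhB gene and cannot break down arabinose. RyhB, a small RNA that pairs with messenger RNAs of iron-using proteins, was made from an arabinose-inducible plasmid, and a plasmid without it served as control vector. Both plasmids were compared in 3 backgrounds with 2 arrays per plasmid, which gives 6 groups of 2. The backgrounds were wild type, a mutant of fur (the iron-responsive repressor of iron uptake genes) and wild type grown with 50 uM FeSO4. Median signals per array lay between 101.4 and 148.9 intensity units, and the number of arrays limits the precision of every value. The highest signal lay between 19858 and 24607 on the 4 fur mutant arrays and between 61651 and 148848 on the other 8. Arrays of 1 group correlated across probe sets at r of 0.974 to 0.992, arrays of different backgrounds at 0.771 to 0.886. Errors of signals are SDs (n = 2 in every group). Log2 differences are on the scale of log2(signal + 50), which understates changes of weak genes, and carry their standard error from limma. The labels do not say whether duplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

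The targeted genes were looked at first. The fur signal was 1448 ± 563 in wild type with vector and 64.4 ± 50.1 in the fur mutant with vector, and the difference of -3.73 ± 0.29 passed the test (adjusted p = 4.9e-07). With RyhB it was 1411 ± 186 in wild type and 104 ± 21.9 in the fur mutant. With FeSO4 the fur signal was 532 ± 47.7 with vector and 600.0 ± 49.3 with RyhB. No probe set carries the locus tag of ryhB, so the induced RNA itself could not be identified here. Whether an intergenic probe set covers it was not examined. Of the 8 arabinose genes tested, 1 passed in the average RyhB effect: araJ, an arabinose-inducible transport protein gene, rose by 0.48 ± 0.09 (adjusted p = 0.0059).

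Averaged over the 3 backgrounds, RyhB lowered sodB and the genes of complex I and of the isc operon. The gene of iron superoxide dismutase, sodB, fell the furthest among named genes, with a log2 difference of -3.61 ± 0.19 (adjusted p = 2.4e-08). Its signal went from 4373 ± 125 to 232 ± 47.9 in wild type, from 5162 ± 53.3 to 487 ± 5.66 in the fur mutant and from 2409 ± 297 to 185 ± 161 with FeSO4. All 13 genes of respiratory complex I, the proton-pumping NADH dehydrogenase, fell, with a median of -1.93. All 8 genes of the isc operon, which builds iron-sulfur clusters, fell with a median of -1.64 (7 under quantile normalization). The strongest rises were those of shiA, a shikimate transporter gene (1.28 ± 0.13), and ompX, an outer membrane protein gene (1.06 ± 0.09).

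**Figure D1:**
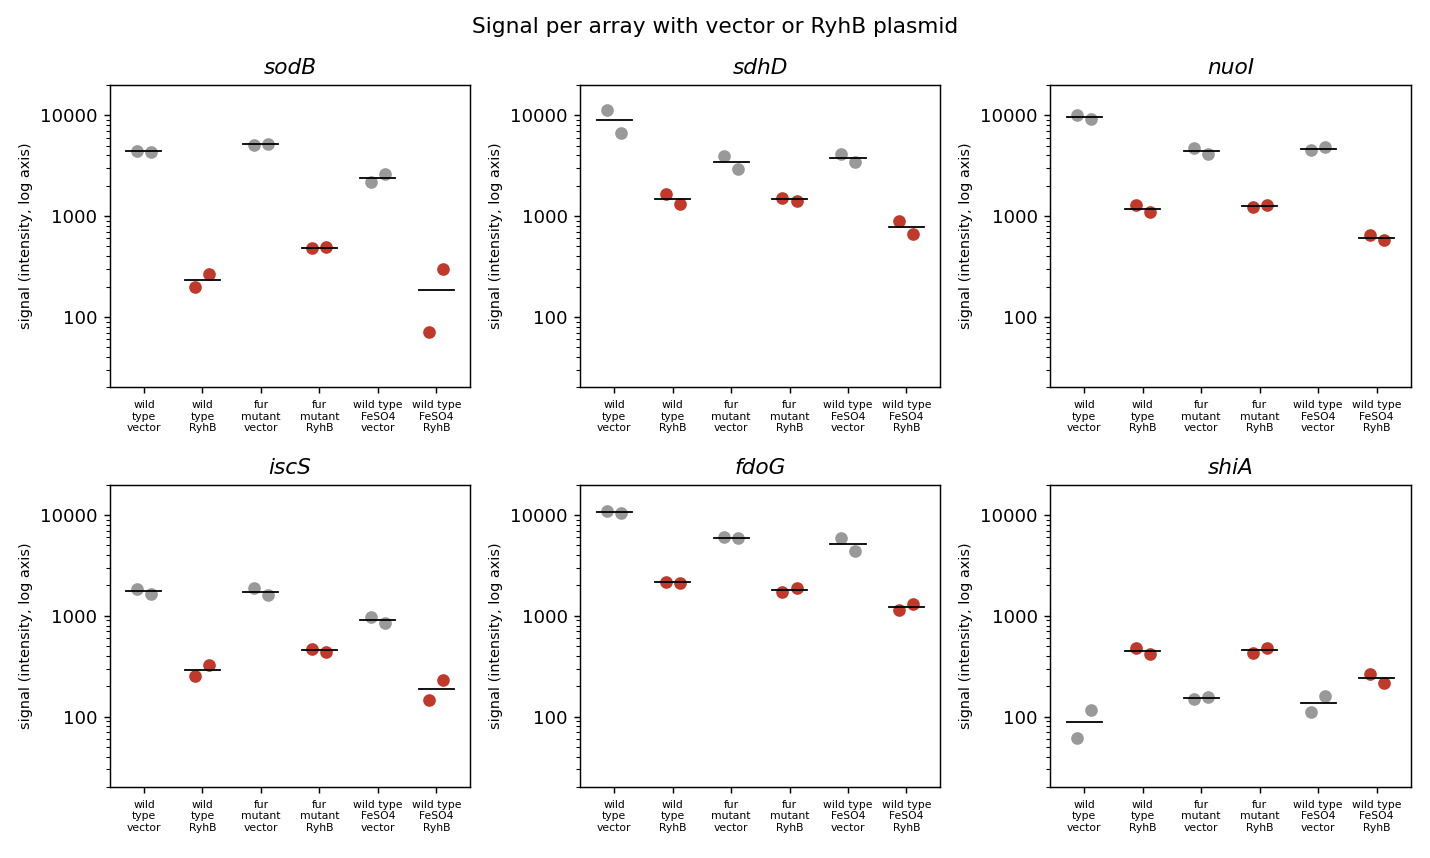
Signal (intensity, log axis) of 6 genes on each of the 12 arrays, grey for vector and red for RyhB, with black lines at group means. In every background both RyhB arrays lie below both vector arrays for sodB, sdhD, nuoI, iscS and fdoG, and above them for shiA.

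Within complex I, nuoI changed by -2.53, nuoH by -2.31, nuoJ by -2.31 and nuoK by -2.05 on the log2 scale. In the isc operon, the cysteine desulfurase gene iscS changed by -2.09, iscX by -2.01, fdx by -1.74 and the scaffold gene iscU by -1.72. Of 9 earlier described RyhB targets, 7 fell and 1 rose (8 and 1 adjusted over the list alone). The falls included succinate dehydrogenase (sdhD -1.97, sdhC -1.90, sdhA -1.60, sdhB -1.50), the fumarase gene fumA (-1.88) and the bacterioferritin gene bfr (-0.81). The rise was that of ftnA, the ferritin gene, at 0.92 ± 0.09, and acnA did not pass. The log2 difference of ftnA was 2.00 in wild type and 0.06 in the fur mutant. Of 6 later described repressed targets, msrB (-1.06), cysE (-0.67) and grxD (-1.25) fell, and both later described activated targets, shiA and the siderophore receptor gene cirA (0.57), rose. The rise of cirA came mostly from the fur mutant (1.62) and was not found in wild type (-0.17) or in the average without the fur mutant arrays (0.04). Among 19 anaerobic respiration genes 11 fell, with the fumarate reductase genes frdC (-1.63) and frdA (-1.48) among them. Among 21 genes of formate dehydrogenases and hydrogenases 8 fell, including fdoH (-2.10), fdoG (-2.00) and hybO (-1.35). In the suf operon, the second cluster assembly system, 3 of 6 genes fell, and all 6 did adjusted over the list alone. Of 20 further iron-sulfur enzymes 8 fell, such as lipA (-0.85), miaB (-0.82) and ispH (-0.61). Other rises were those of oppA (0.94), an oligopeptide-binding protein gene, kgtP (0.80), an alpha-ketoglutarate transporter gene, ygdQ (1.01), ybaK (0.91) and yncE (0.88). Without the fur mutant arrays the calls of yncE, the suf gene sufB, and lipA and rimO of the further iron-sulfur enzymes were lost.

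In total 239 of 3707 probe sets passed in the average, 159 lower and 80 higher. Camera called 11 of 24 lists, and 8 of them held with an estimated correlation. The calls lost were those of Fur-repressed iron uptake (9 of 37 genes lower and 1 higher, adjusted p = 0.16 with an estimated correlation), ribosomal proteins (0 of 54, adjusted p = 0.51) and flagella and chemotaxis (2 of 20 higher, adjusted p = 0.31). The median of the ribosomal proteins was 0.11 and turned to -0.02 under quantile normalization. Lists without a call were other Fur-repressed genes, iron storage, the citric acid cycle outside earlier targets, cytochrome oxidases, the peroxide and superoxide responses, cysteine and sulfate assimilation, arabinose genes, heat shock, stationary phase, catabolite-controlled carbon uptake, the SOS response and other metal transport. The count fell to 145 (105 lower, 40 higher) on the 8 arrays without the fur mutant and to 42, all lower, by the submitters' rule of a ratio above 2 in each background. The rises fell from 80 to 46 and 53 without fur mutant RyhB replicates 1 and 2. Among 100 relabellings of the arrays within backgrounds, 12 (the real one included) called at least 11 lists, so chance is not excluded for that number. Relabellings that keep 1 background as it was retain part of the RyhB effect, so these 12 do not show that chance explains it.

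In wild type, RyhB changed 172 probe sets, 110 lower and 62 higher. The furthest falls were those of sodB (-3.98 ± 0.34), nuoI (-2.97 ± 0.13), nuoH (-2.69 ± 0.16), frdC (-2.63 ± 0.29) and sodA, the manganese superoxide dismutase gene (-2.63 ± 0.21). All 13 complex I genes fell (median -2.08), as did 7 of 8 isc genes (median -1.83). Genes of Fur-repressed iron uptake fell as a group in 14 of 37 cases (20 adjusted over the list alone) with none higher and a median of -0.82. The ferritin gene ftnA rose from 894 ± 40.9 to 3754 ± 574, a log2 difference of 2.00 ± 0.16 (adjusted p = 2.6e-06).

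Among the iron uptake genes, exbD (-2.05) and exbB (-2.00), which energise outer membrane receptors, fell the furthest, followed by the reductase gene fhuF (-1.83) and the ferric citrate transport gene fecD (-1.68). In this comparison the 62 rises became 25 when the groups were fitted alone, 25 by the ratio rule, 40 without an intensity trend and 39 without RyhB replicate 1. The iron uptake list's median was -0.53 without RyhB replicate 1 and -0.48 without vector replicate 1. Earlier described targets fell in 6 of 9 cases and ftnA rose. The signal of sdhD was 9035 ± 3329 with vector and 1494 ± 243 with RyhB (-2.52), and fumA changed by -2.49 and sdhC by -2.43. The aconitase gene acnB, outside that list, changed by -1.95. Rises included shiA (1.88), ygdQ (1.74), ompX (1.49) and the chaperone gene htpG (1.26). Others were those of the cysteine tRNA gene cysT (1.20), the flagellar gene flgB (1.19), oppA (1.18), brnQ (1.16) and kgtP (1.13). The calls of htpG and flgB were lost with the groups fitted alone, and that of htpG also without the signal filter. In at least 1 fit without 1 array the calls of htpG, flgB and fhuF were each lost. Camera called 11 lists, of which earlier targets, complex I, isc, iron uptake, formate dehydrogenases and hydrogenases, and the further iron-sulfur enzymes held with an estimated correlation. The other 5 did not: later repressed targets, suf and anaerobic respiration (adjusted p = 0.053 each with an estimated correlation), ribosomal proteins (0 of 54, adjusted p = 0.29) and catabolite-controlled carbon uptake (1 of 27 lower, adjusted p = 0.45). The ribosomal protein median of 0.24 turned to -0.01 under quantile normalization.

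In the fur mutant, RyhB changed 68 probe sets, 56 lower and 12 higher. The test uses 1 shared spread, but the median SD on the log2 scale differed between groups. It was 0.08 with RyhB and 0.10 with vector in the fur mutant, and 0.17 and 0.16 in wild type. With each background fitted alone the counts were 115 in the fur mutant and 118 in wild type. The counts of 68 and 172 therefore do not by themselves show a weaker response in the fur mutant. Falls were again led by sodB (-3.28 ± 0.34), followed by nuoJ (-1.88 ± 0.14), nuoG (-1.83 ± 0.13), iscS (-1.83 ± 0.19) and fumA (-1.78 ± 0.20). All 13 complex I genes fell (median -1.62) and 7 of 8 isc genes (median -1.37). The furthest rise was that of flu, which encodes the phase-variable surface adhesin antigen 43 (1.96 ± 0.17, adjusted p = 2.2e-05), with yeeR (1.49) and yeeS (1.20) next to it. The signal of cirA went from 2696 ± 44.4 to 8388 ± 467, a log2 difference of 1.62 ± 0.20.

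Of the 37 iron uptake genes, cirA alone passed the test in the fur mutant, and the list's median was 0.02. Earlier described targets fell in 6 of 9 cases, including sdhB (-1.40) and sdhA (-1.36), while ftnA stood at 416 ± 15.3 with vector and 438 ± 84.6 with RyhB. The later repressed targets grxD (-1.57), cysE (-0.90) and msrB (-0.84) fell and shiA rose (1.31). Other rises were those of yncE (1.24), ygiM (1.05), oppA (0.91), purU (0.90) and rnd (0.87). The calls of sdhA, cysE, msrB, shiA, ygiM, oppA, purU and rnd were each lost in at least 1 fit without 1 array. Their direction held in these fits. Camera called 10 lists, and 7 held with an estimated correlation: earlier and later repressed targets, complex I, isc, suf, anaerobic respiration, and formate dehydrogenases and hydrogenases. The further iron-sulfur enzymes (0 of 20, adjusted p = 0.076), cytochrome oxidases (1 of 8, adjusted p = 0.59) and flagella and chemotaxis (0 of 20, adjusted p = 0.52) did not. The count was 44 and 40 without RyhB replicates 1 and 2, 39 without vector replicate 1, and 115 when the 4 fur mutant arrays were fitted alone. The 12 rises became 4 and 3 without RyhB replicates 1 and 2, 4 and 7 without vector replicates 1 and 2, and 29 with these arrays alone.

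In wild type with FeSO4, RyhB changed 89 probe sets, 75 lower and 14 higher. The furthest falls were those of sodB (-3.57 ± 0.34), nuoI (-2.84 ± 0.13), nuoJ (-2.63 ± 0.14) and the hydrogenase 2 genes hybO (-2.39 ± 0.19) and hybC (-2.28 ± 0.24). All 13 complex I genes fell (median -2.04) and 7 of 8 isc genes (median -1.53). Among earlier described targets 7 of 9 fell and ftnA rose (0.71 ± 0.16). The periplasmic nitrate reductase gene napF changed by -2.22, fdoH by -2.28, sdhD by -2.22, nuoC by -2.22 and bfr by -1.38. Of the 37 iron uptake genes 3 fell (fecE -1.46, exbB -1.09, fecC -1.08) and 1 rose (fiu 0.88). The calls of fecC and fiu were lost with the groups fitted alone. That of fiu was also lost with a replicate block, and that of fecC without the signal filter or the intensity trend. Further rises were those of clsB (1.83, from 45.5 ± 6.43 to 294 ± 85), ompX (1.08), galP (0.89), kgtP (0.76), ndk (0.75), garL (0.77) and dtpA (0.68). Of these, galP, garL and dtpA lost the call with the groups fitted alone, and clsB with a pseudocount of 10 or 1. The calls of kgtP, ndk and ftnA were each lost in at least 1 fit without 1 array. That of ftnA was also lost without the intensity trend. The 14 rises became 26 under quantile normalization, 28 without the signal filter, 25 by the ratio rule and 6 without vector replicate 1. The isoleucine tRNA gene ileX rose by 1.90, on a probe set shared between sequences. Camera called 9 lists, and earlier targets, complex I, isc, and formate dehydrogenases and hydrogenases held with an estimated correlation. The other 5 did not: later repressed targets (adjusted p = 0.11), iron uptake (adjusted p = 0.53), anaerobic respiration (adjusted p = 0.12), cytochrome oxidases (adjusted p = 0.45) and flagella and chemotaxis (adjusted p = 0.34).

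**Figure D2:**
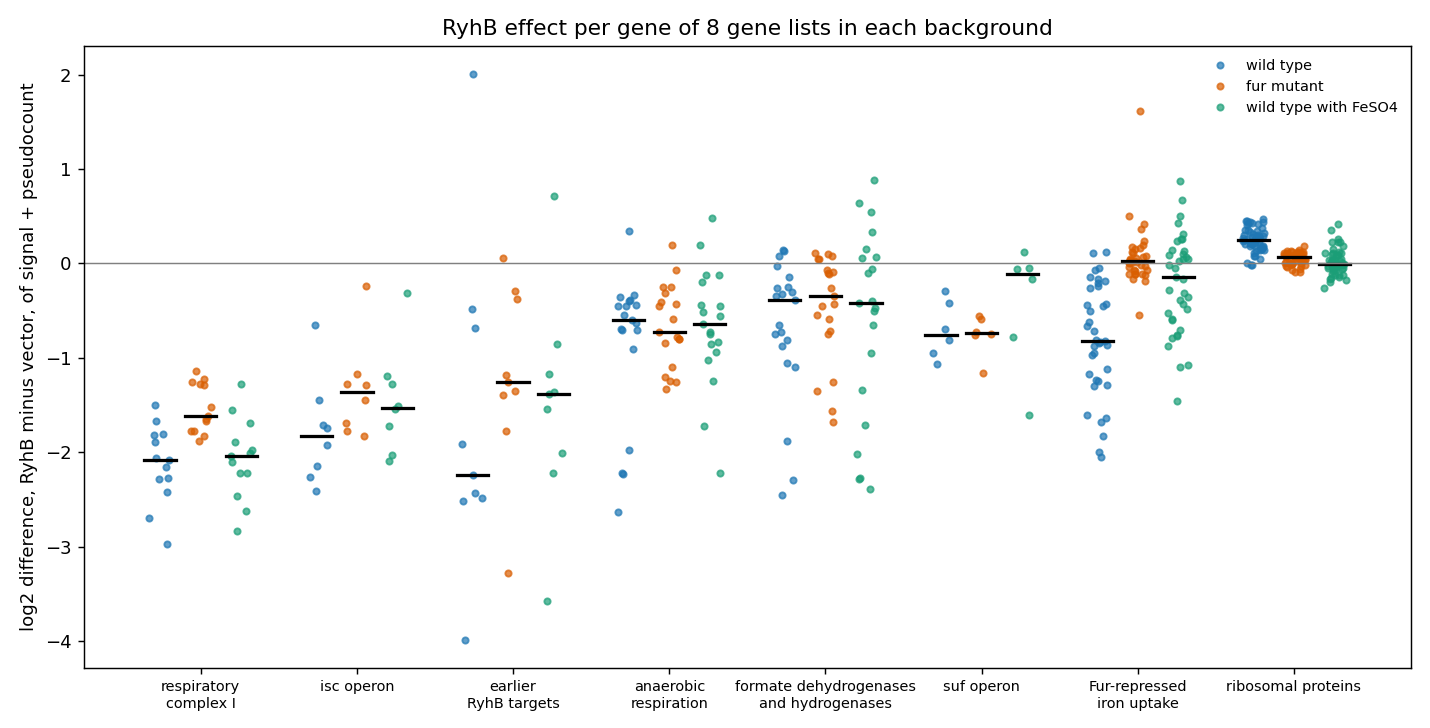
Log2 difference (RyhB minus vector, of signal + 50) of each tested gene in 8 gene lists, by background, with black lines at medians. Complex I medians lie at -2.08, -1.62 and -2.04 in wild type, fur mutant and FeSO4, and those of iron uptake at -0.82, 0.02 and -0.15.

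The 3 backgrounds shared no arrays, and 44 probe sets were lower with RyhB in all of them, where independent lists of these sizes would share 0.034. That number is too low a yardstick, because the 3 comparisons share 1 estimate of the spread per probe set. Genes of 1 operon also do not vary independently. The 44 comprised 37 gene probe sets and 7 intergenic ones. The genes were sodB, all 13 complex I genes, 7 isc operon genes (iscR was the exception), sdhA to sdhD, fumA, fdoG, fdoH, fdoI, frdA, grxD, msrB, mrp, pepB, pflA, trxA and ycfP. The 44 became 47 under quantile normalization and 39 without the signal filter, and fewer still in some fits without 1 fur mutant array. In the fur mutant the call of sdhC was lost with other pseudocounts, under quantile normalization or median centring, and without the filter or intensity trend. That of sdhD was lost without the filter or trend, and those of sdhA, frdA and msrB in some fits without 1 array. With FeSO4 those of sdhB and grxD were lost without the trend. By limma, 0 probe sets were higher in all 3, with 18 at an unadjusted p under 0.05 in each. That 0 was not stable: it became 4 under quantile normalization and 1 with a replicate block. It was 2 without wild-type RyhB replicate 1 or either wild-type vector replicate, and 1 without wild-type RyhB replicate 2, fur mutant vector replicate 2 or RyhB replicate 1 with FeSO4. Wild type and the fur mutant shared 4 rises and wild type and FeSO4 shared 5, while the fur mutant and FeSO4 shared 0. Across the 3707 probe sets, which are not independent replicates, RyhB effects correlated at r = 0.51 between wild type and fur mutant, 0.44 between wild type and FeSO4, and 0.49 between fur mutant and FeSO4.

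The difference of the RyhB effect between fur mutant and wild type was tested directly. It passed for 8 of 3707 probe sets. The gene exbB fell in wild type (-2.00) and stood at 3968 ± 278 with vector and 4172 ± 41.9 with RyhB in the fur mutant, a difference of 2.07 ± 0.19 (adjusted p = 2.7e-04). The difference was in the same direction for exbD (1.96 ± 0.24), sodA (1.85 ± 0.30) and nuoI (1.20 ± 0.19), all of which fell in wild type. The rise of ftnA was smaller there (-1.95 ± 0.23), and cirA (1.79 ± 0.28) and flu (2.21 ± 0.24) responded more in the direction of a rise. The eighth was an intergenic probe set (1.44). As a group, the iron uptake genes differed by a median of 0.93, with 3 of 37 higher (18 adjusted over the list alone), and camera's call held with an estimated correlation (adjusted p = 0.049). The isc operon differed by 0.50 (adjusted p = 0.049 with an estimated correlation), and complex I by 0.54 (adjusted p = 0.058 with an estimated correlation). Camera called 8 lists in all. The others were lost with an estimated correlation: earlier targets (adjusted p = 0.23), other Fur-repressed genes (0.44), formate dehydrogenases and hydrogenases (0.18), cytochrome oxidases (0.47) and ribosomal proteins (0.37), whose median of -0.19 turned to 0.01 under quantile normalization. The count was 16 without wild-type RyhB replicate 2, 19 without wild-type vector replicate 2, 5 and 4 without fur mutant RyhB replicates 1 and 2, and 4 without fur mutant vector replicate 2. It was 17 with a replicate block, 5 without the signal filter and 4 without an intensity trend. The calls of sodA, cirA and nuoI were lost in some of these fits, and those of exbB, exbD, ftnA and flu in none that tested them.

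**Figure D3:**
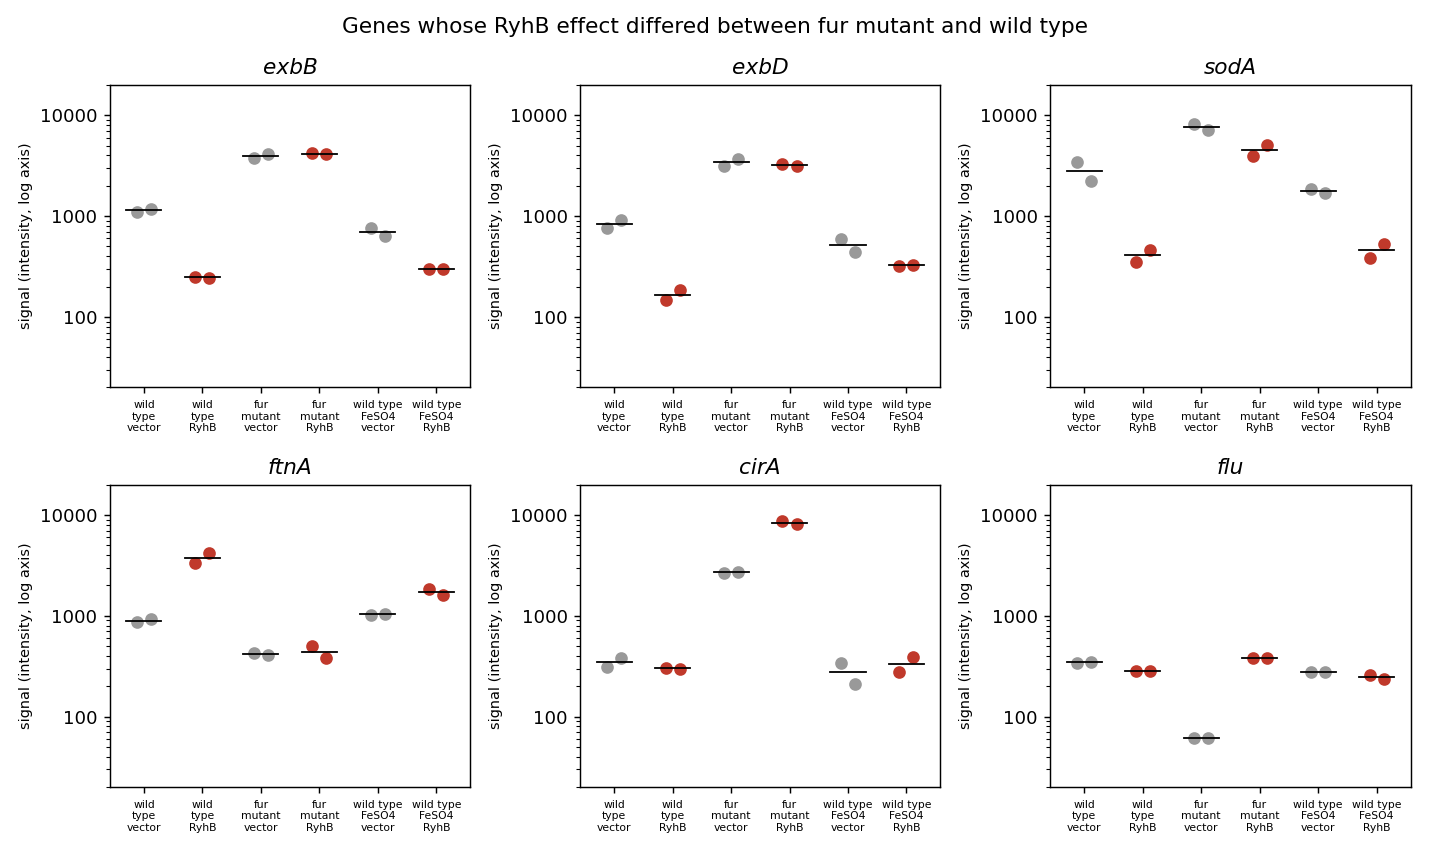
Signal (intensity, log axis) of exbB, exbD, sodA, ftnA, cirA and flu on each of the 12 arrays, grey for vector and red for RyhB, with black lines at group means. The flu signal is 61.5 ± 0.212 in the fur mutant with vector and 383 ± 2.4 with RyhB.

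Between FeSO4 and no FeSO4, the RyhB effect passed the test of the difference for 0 of 3707 probe sets in limma, with 361 at an unadjusted p under 0.05. The smallest p-values were those of acnB (1.50 ± 0.25), exbD (1.45 ± 0.24) and hybC (-2.03 ± 0.34), each with an adjusted p of 0.054. Iron uptake genes differed by a median of 0.55, with an adjusted p of 0.22 with an estimated correlation. Camera called 8 lists, none with an estimated correlation: iron uptake, isc, iron storage, the superoxide response and heat shock (adjusted p = 0.22 each), cytochrome oxidases (0.41), and ribosomal proteins and catabolite-controlled carbon uptake (0.40 each). The count of probe sets was 3 after median centring, 4 under the stricter filter and 1 without an intensity trend. It was 2 and 7 without wild-type RyhB replicates 1 and 2, 3 without wild-type vector replicate 2 and 1 without RyhB replicate 2 with FeSO4.

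In the strains with vector, the fur mutant differed from wild type in iron uptake and other Fur-repressed genes. Of 37 tested Fur-repressed iron uptake genes 33 were higher and none lower (34 adjusted over the list alone), with a median of 1.96. The enterobactin genes entH (5.22 ± 0.33) and entA (4.79 ± 0.22) and the receptor genes fiu (4.66 ± 0.19) and fepA (4.50 ± 0.26) were among the furthest. All 10 other Fur-repressed genes were higher, such as nrdI (3.19) and bfd (3.18), as were all 6 suf genes (median 2.21). All 13 complex I genes were lower (median -1.39), and 44 of 54 ribosomal protein genes were lower and 4 higher. The ribosomal protein counts became 26 and 6 under quantile normalization.

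Large differences were also found outside iron metabolism. The small RNA genes spf (5.19) and ssrS (4.73) were higher, as were ilvL (4.07) and the tRNA genes leuZ (4.38), leuQ (4.53) and proL (4.39). The last 2 are on probe sets shared between sequences. The tRNA share of the summed signal was 9.72 to 10.97% on the fur mutant arrays and 3.5 to 6.82% on the others. The rRNA share moved the other way, at 5.04 to 6.06% on the fur mutant arrays and 10.58 to 18.83% on the others. Apart from fur itself, the furthest falls were those of srlE (-2.96) and srlB (-2.11) of sorbitol uptake, mglA (-2.27), the nitrate reductase gene narG (-2.24), nanT (-2.23), galT (-2.17), gutQ (-2.14), pgl (-2.10) and lldR (-2.05). Of 7 SOS genes 5 were higher (4 under quantile normalization or median centring), among them dinI (2.60), recA (1.87) and lexA (1.67), and of 14 heat shock genes 9 were higher and 1 lower. Of 8 cytochrome oxidase genes 7 were lower, and of 8 arabinose genes 6. In total 1768 probe sets passed, 990 lower and 778 higher, and 947 by the ratio rule (461 lower, 486 higher). Under the stricter filter 764 were lower and 483 higher. Camera called 12 lists, none of them with an estimated correlation, where adjusted p lay between 0.09 (iron uptake, suf) and 0.47 (anaerobic respiration). Those not yet named were formate dehydrogenases and hydrogenases and the further iron-sulfur enzymes. Each background lay on its own arrays, so outside the Fur-repressed genes the mutation and any difference in culture or hybridisation between array sets cannot be told apart. For the Fur-repressed genes a difference in culture stays open, and a signal-dependent effect of hybridisation is argued against by draws of other genes. This and the next comparison share the wild-type vector arrays.

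The effect of FeSO4 was examined in the strains with vector. The ribosomal protein gene rplS (-4.21 ± 0.13), the threonine dehydrogenase gene tdh (-3.94 ± 0.21), rplT (-3.04 ± 0.16), the ribonuclease E gene rne (-3.02 ± 0.18) and the galactose transporter gene galP (-3.19 ± 0.18) were lower. The initiator tRNA genes metY (4.55), metW (4.14), metZ (4.08) and metV (4.04) were higher, on probe sets shared between sequences. The lipid A modification genes arnC (3.59 ± 0.19), arnB (3.11 ± 0.35) and eptA (3.03 ± 0.25) were higher too. Of 37 iron uptake genes 12 were lower and 2 higher (16 and 2 under quantile normalization, median -0.60), with fecB (-1.71) and feoB (-1.56) the furthest down, and fur itself was lower (-1.31). Among complex I genes 10 of 13 were lower and 1 higher, and of 8 further citric acid cycle genes 7 were lower, such as gltA (-2.19) and mdh (-1.81). Other far changes were those of ybgE (-3.40), b0667 (-3.24), araG (-2.96), mglC (-2.88) and plaP (-2.87) downward, and ubiK (3.27), yciA (2.92) and rraB (2.76) upward. In total 1633 probe sets passed, 761 lower and 872 higher, and 828 by the ratio rule (398 lower, 430 higher). The excess of rises turned into an excess of falls under quantile normalization (838 lower, 810 higher), median centring (836 and 783) and the stricter filter (580 and 571). Camera called complex I, iron uptake and the citric acid cycle, and none held with an estimated correlation (adjusted p = 0.72 for each). FeSO4 lay on its own array set, so its effect and that of the array set cannot be told apart.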

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

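The tests of Fur repression, of a weaker response of all genes, of RyhB acting on flu in every background and of a phase switch were chosen after the results were seen. The direct test of the difference in RyhB effect singled out 8 probe sets between fur mutant and wild type: exbB (2.07), flu (2.21), ftnA (-1.95), exbD (1.96), cirA (1.79), nuoI (1.20), sodA (1.85) and 1 intergenic probe set (1.44).

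Iron uptake genes fell with RyhB in wild type and not in the fur mutant. The median difference of 0.93 over the list passed camera with both correlations (adjusted p = 0.049 with an estimated correlation). That test restates the pattern, so it adds no support for repression by Fur, which stays open. If all genes responded more weakly on the fur mutant arrays by the ratio of the complex I medians (0.78), the list's median there would be -0.64. The median was 0.022, which argues against a weakening in that proportion. Its bootstrap interval of -0.023 to 0.064 resamples genes, many of them in shared operons, and so does not measure the spread between arrays. The list's wild-type medians without 1 array were added after seeing the data. Without vector replicate 1 the wild-type median was -0.48, the weakest of the fits without 1 array. It stayed beyond the limit of -0.41 that a cause in 1 array would have crossed. The bootstrap interval (-0.87 to -0.36), which was not part of that limit and resamples genes and not arrays, includes -0.41. A part played by that array therefore stays open.

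The flu signal rose with RyhB in the fur mutant, where the vector arrays stood at 61.5 ± 0.212 and all other groups between 246.8 and 383. The difference from wild type of 2.21 (adjusted p = 0.0010) is how flu was picked, but FeSO4 was not used to pick it, and there RyhB changed flu by -0.14 with an upper bound of 0.27, which argues against RyhB raising flu in every background. The neighbours yeeR (1.49) and yeeS (1.20) rose as well in the fur mutant. The call of yeeS (limma, adjusted p = 0.032) was lost without the signal filter and with a replicate block. Those of yeeR and yeeS were each lost in at least 1 fit without 1 fur mutant array, with the direction kept. Across groups yeeR did not follow flu. In wild type flu stood at 347 ± 3.18 with vector and 283 ± 1.06 with RyhB. There yeeR stood at 79 ± 6.86 and 83.7 ± 34.6, near its 103 ± 15.6 in the fur mutant with vector. The signal of yeeS, like that of flu, was lowest in the fur mutant with vector (38.55 ± 10.5). It lay between 112.9 and 287.6 in all other groups. A phase switch of flu between cultures and RyhB acting in the fur mutant both stay open, and no measurement here tells them apart.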

How the results depend on the processing

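The mean of 2 backgrounds without the fur mutant arrays and the iron uptake medians without single arrays were added after seeing the data. Over 390 pairs of a named gene and a comparison that passed, 5497 alternative values were computed. The direction held in all of them and the call in 5107, with 390 calls lost. For genes picked because their groups do not overlap, no pseudocount and no single array left out can reverse the direction. The filter and the intensity trend leave each difference unchanged. The held direction was thus largely fixed in advance, and the ratio rule was not part of this count. Total counts that moved by over 1.5 times follow. For the average RyhB effect the ratio rule gave 42 and the fit without the fur mutant arrays 145, against 239. Of the 239, 142 were among those 145. In the fur mutant the 4 arrays alone gave 115 and single arrays left out 39 to 52, against 68. The ratio rule gave 947 for the fur mutation and 828 for FeSO4. For the difference between fur mutant and wild type, no filter gave 5, no intensity trend 4 and single arrays left out 4 to 19, against 8. For the difference between FeSO4 and no FeSO4, median centring gave 3, the stricter filter 4, no trend 1 and single arrays left out 0 to 7, against 0. With an estimated correlation camera called 6 lists in wild type, 4 with FeSO4, 0 for the fur mutation and 0 for FeSO4 in vector strains, and directional fry called 14 for the last. For the difference between fur mutant and wild type camera then called 2 (fry 5) against 8, and for that between FeSO4 and no FeSO4 0 (fry 2) against 8. The cause was not tested. A lone array left in a group is assumed to vary like the other groups. The average fitted on its groups alone is the same fit, so it has no value of its own.

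Replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at 0.072, -0.072 and 0.072 within the 3 backgrounds. With a replicate block the difference between fur mutant and wild type gave 17 calls against 8, and the total of no other comparison of probe sets moved by over 1.5 times, while the rises shared by all 3 backgrounds went from 0 to 1. Among the rises counted by themselves, those in wild type ranged down to 25 (groups alone, ratio rule) against 62, those with FeSO4 from 6 (without vector replicate 1) to 28 (no filter) against 14, and those shared by all 3 backgrounds up to 4 (quantile normalization) against 0. In the average the rises fell to 46 without fur mutant RyhB replicate 1 and to 0 by the ratio rule, against 80, and in the fur mutant they ranged from 3 (without RyhB replicate 2) to 29 (groups alone), against 12. Weak signals limit genes near the pseudocount of 50, where fold changes are understated.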

Other observations

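The tests of each list by itself, of separate array sets, of lost Fur repression and of a labelling or scan effect were chosen after the results were seen. Of the 100 relabellings of the arrays within backgrounds, drawn from 108, only the real one gave as many as 239 probe sets. That count was for the average RyhB effect, and the highest other was 83. A share of 1 of 100 is the smallest that this test can give, so chance is unlikely for that count but not excluded. For the number of lists, 12 of 100 gave at least the real 11 and the highest other gave 15, so chance cannot be excluded for that number. Taken list by list, a test chosen after that count was seen, the median lay as far from 0 in under 5 of 100 relabellings for 7 of the 11 lists called. These were complex I, isc, suf, earlier and later repressed targets and anaerobic respiration (1 each, the real one), and formate dehydrogenases and hydrogenases (2). It did so in 10 for iron uptake, 18 for the further iron-sulfur enzymes, 9 for ribosomal proteins and 5 for flagella and chemotaxis. Relabellings that keep 1 background as it was retain part of the RyhB effect, which raises these counts.

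Between fur mutant and wild type with vector, 1768 of 3707 probe sets differed. Quantile normalization called 1791, 1690 of them among the 1768, which argues against a different distribution of signals on the array sets as the whole cause. Of 47 Fur-repressed genes 43 were higher in the fur mutant, and at most 20 in 1000 draws of as many other genes, each among the 50 nearest in signal, which argues against a labelling or scan effect that depends on signal for these genes. Loss of Fur repression would raise the iron uptake genes, and 33 of 37 were higher against at most 16 in such draws, but a difference between cultures that no label names stays open. Arrays of different backgrounds correlated at 0.886 at most and arrays of 1 background at 0.958 at least. For other genes the mutation and a separate culture, labelling or scan cannot be told apart, because each background lies on its own arrays.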
